A study of Mus musculus with 18 samples.

How the data were processed

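Messenger RNA was measured by polyA-selected RNA sequencing in 4T1 cells, a mouse mammary carcinoma line from a BALB/c animal that is used as a model of triple-negative breast cancer. Per the labels' protocols, the cells carried a doxycycline-inducible hairpin, were induced with 2 µg/ml doxycycline for 6 days, and were lysed and run on sucrose gradients. RNA was taken with Trizol from unfractionated lysate (input) and from pooled light and pooled heavy polysome fractions, cleaned on Zymo columns and made into stranded libraries. The hairpin was either non-silencing (NSi, the control arm) or directed against Dap5 (shDap5); DAP5 protein is the product of the gene Eif4g2. The groups came from the sample titles: 2 arms by 3 fractions, with 3 libraries in each of the 6 groups and 18 in all. Nothing in the labels says whether libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical in part.

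The authors deposited raw counts per gene symbol, 1 column per library, with no normalization. Per the submitters' processing notes, reads were aligned with Bowtie to the mouse build mm9; the version of the aligner, the counting program, the annotation, the use of strand and the treatment of reads shared between genes are not given in the sources used here. Each library listed 35976 symbols. Of these, 27 were written as spreadsheet dates in place of gene symbols, and 4 of those shared a date name with another; no date-like symbol is named in the text. Near-identical families (histones, ribosomal proteins, glycolytic genes with many pseudogenes such as Gapdh, the Serpina3 cluster) and overlapping or antisense genes are uncertain, because shared reads may have been split or dropped. Coordinates are left out, because the annotation at hand was of another build (GRCm38).

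Total counts ran from 30385863 to 71331978 per library. A symbol with 0 counts could still have stood at up to 3 counts, which is 0.0421 to 0.0987 CPM (library-scaled counts as edgeR gives them) depending on the library; such limits cover counting error only. No pair of replicates was alike within sampling noise: chi-square per degree of freedom between replicates of a group was 9.57 at the lowest.

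Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (robust fit, TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15). All 18 libraries were fitted together with 1 mean per group, which left 12 residual degrees of freedom and a common biological coefficient of variation of 0.227. After the filter 15072 genes were tested. Comparisons of shDap5 with NSi were made within input, light and heavy polysomes. The change on polysomes beyond that in the input was tested as an interaction (heavy relative to input, light relative to input), as was the shift along the gradient (heavy relative to light), and NSi heavy was compared with NSi light as the background. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and "called", "rose" and "fell" mean an adjusted p under 0.05. CPM values are TMM-scaled; the standard error (SE) of a log2 change is its size divided by the square root of F.

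Gene lists were tested with camera (limma 3.58.1) on the edgeR z-scores with a preset correlation of 0.01 between genes, two-sided, adjusted by Benjamini-Hochberg over the 31 lists with at least 3 tested members, out of 34 lists (28 of genes and 6 of markers for other cell types). The same test with a correlation estimated from the residuals is given beside it. The test fry asked whether members moved, on balance, in a common direction, without comparing them with other genes. The design, the lists, the alternatives that are not said to be added and the rule for naming genes were set before the data were examined.

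Named genes were Eif4g2 in every comparison; the 10 largest rises and 10 largest falls (5 and 5 in light, in light relative to input, in heavy relative to light and in control heavy against light) among called genes with a mean of at least 5 CPM whose 3 libraries of each arm did not overlap, a pattern that chance gives to 10% of genes; and up to 4 members of each list with the smallest p-values. Where fewer than 5 genes passed in a direction, the 5 with the smallest p-values that met the other conditions are named and are said not to have passed. In the relative comparisons the rule on overlap used differences between fractions of the same number, a pairing that mostly failed between input and polysomes (below). Where the Results give the genes with the smallest p-values of a comparison, only genes that met these conditions are ranked. Not every gene that the rule takes is named in the text. A gene outside this rule is said to have been chosen after its values were seen.

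The libraries carry replicate numbers in their titles, and whether a number pairs libraries was checked from the correlation, across 8435 genes, of each library's deviation from its group mean; genes are not independent replicates. NSi and shDap5 libraries of the same number deviated together within a fraction (r 0.137 to 0.337 in input, 0.56 to 0.816 in light, 0.552 to 0.834 in heavy), and so did light and heavy libraries of the same number (0.498 to 0.727 in NSi, 0.624 to 0.746 in shDap5). This was far weaker in input, where an NSi and a shDap5 library of different numbers reached 0.149, above the lowest value for the same number; between the arms on heavy polysomes no pair of different numbers exceeded 0.0287. NSi input and polysome libraries of the same number mostly did not (-0.341 to -0.0863 with light, -0.324 to 0.107 with heavy). The shDap5 inputs did for number 1 (0.503 with light, 0.455 with heavy) and number 2 (0.333 and 0.228) but not for number 3 (-0.235 and -0.255), whose input deviated with light 1 (0.523) and heavy 1 (0.521). A fit with a replicate block within each fraction was therefore added after the data were seen, beside the block by number that was set in advance, and both are given where they change a call or move a count by over 1.5 times.

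Other alternatives were RLE size factors, total counts without a composition factor, no filter on low counts, only the groups compared, DESeq2 1.42.0, and leaving out each arm and number in turn. Leaving out shDap5 input 2 or shDap5 input 3 alone, and a block within fraction with a correction for coding length and GC content (GENCODE vM21, with a coding length for 12871 tested genes, 85.4%), were added after the data were seen. For the relative comparisons the same correction, with and without the block, was also applied to the 29 lists with at least 3 members that have a coding length. Protein was not measured in this series, so the amount of DAP5 is not known from these data.

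The edgeR step was tested on simulated counts drawn from the real means and library sizes. Changed genes were drawn from the 10308 of 15072 tested genes with a mean of at least 5 CPM. The rates below therefore do not cover genes at lower levels. Of 67 genes changed by 2-fold, it called 59.7% in the input comparison, 68.7% in light and 64.2% in heavy, but 23.9% in heavy relative to input, 17.9% in light relative to input and 23.9% in heavy relative to light. Of 66 genes changed by 4-fold, it called 97%, 92.4%, 93.9%, 93.9%, 89.4% and 90.9% in the same order. Between 1 and 7 unchanged genes were called per comparison, and 0 of 100 random lists. Each gene was drawn independently, without the shared deviation of libraries of a number or joint variation of list members. These rates therefore do not give the false calls to be expected in the real libraries.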

Results

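Polyadenylated RNA was counted per gene in 18 libraries from 4T1 mouse mammary carcinoma cells. Cells expressed a non-silencing hairpin (NSi) or a hairpin against Dap5 (shDap5). RNA came from whole lysate (input), light polysomes or heavy polysomes, with 3 libraries per arm and fraction. Total counts ran from 30385863 to 71331978 per library. Genes with at least 1 count numbered 19099 to 21513 in inputs, 18290 to 20030 on light and 17267 to 18909 on heavy polysomes. Malat1, a nuclear noncoding RNA, stood at 307 ± 16.5 CPM (SD, n = 3) in NSi inputs, 55.7 ± 3.56 on NSi light and 11.2 ± 5.69 on NSi heavy polysomes. In shDap5 it stood at 365 ± 71.9, 27.8 ± 11 and 8.95 ± 2.93 CPM. Markers of cell types that a tumour would bring along were low in NSi inputs. The median member of the endothelial, macrophage, fibroblast, lymphocyte, adipocyte and red cell lists lay at 0.268, 0.0896, 0.0866, 0.0106, 0.0105 and 0.0104 CPM. In shDap5 inputs the same medians were 0.1495, 0.0781, 0.0539, 0.00545, 0.0142 and 0.0054 CPM. Macrophage Cd68 reached 43 CPM and Pdgfra of the fibroblast list 35 CPM in NSi inputs, against 24.6 and 25.3 CPM in shDap5 inputs. Other members, chosen after their values were seen, also differed. Csf1r of the macrophage list stood at 2.26 CPM in NSi and 10.5 in shDap5 inputs, and Fabp4 of the adipocyte list at 2.73 and 0.504.

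Eif4g2, which encodes the translation initiation factor DAP5 and is the target of the hairpin, was lower in shDap5 than in NSi in all 3 fractions. On light polysomes it stood at 1022 ± 275 CPM in NSi and 338 ± 80.6 in shDap5 (SD, n = 3 each; 33.1% of NSi), and on heavy polysomes at 782 ± 108 and 286 ± 68.5 (36.5%). The edgeR log2 change was -1.60 (SE 0.26, adjusted p = 0.00204) on light and -1.45 (SE 0.26, adjusted p = 0.00349) on heavy polysomes. In input Eif4g2 stood at 803 ± 46.3 CPM in NSi and 534 ± 173 in shDap5 (66.5%). Single shDap5 inputs stood at 592, 340 and 671 CPM, all below the lowest NSi input at 760 CPM. That difference missed the edgeR test (log2 -0.59, SE 0.26, adjusted p = 0.202). With replicate number as a block it also missed it (log2 -0.60, edgeR adjusted p = 0.0783), and with a block within each fraction it passed (log2 -0.64, SE 0.14, adjusted p = 0.00454). The larger reduction on polysomes was not called over all genes: Eif4g2 was at -0.86 (SE 0.36, edgeR adjusted p = 1) on heavy and -1.01 (SE 0.36, adjusted p = 1) on light polysomes relative to input.

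**Figure D1:**
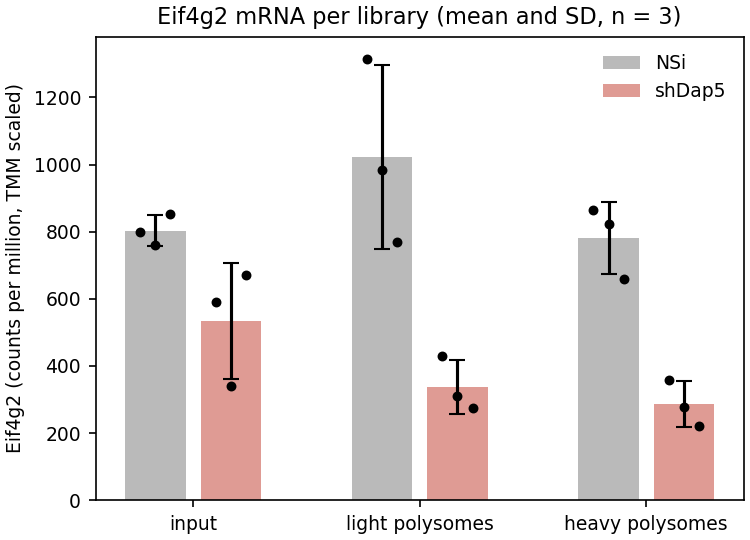
Eif4g2 in CPM (TMM-scaled) in input, light and heavy polysomes; bars are means of 3 NSi (grey) or 3 shDap5 (red) libraries, error bars SDs and points single libraries. The shDap5 mean is 66.5% of the NSi mean in input, 33.1% on light and 36.5% on heavy polysomes.

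The input comparison asked how the mRNA content differed in cells with the hairpin against Dap5. Each arm is 1 line and uninduced cells were not sampled. In every comparison of the arms, a difference that predates induction therefore cannot be told apart from a response to the hairpin. Epithelial genes were higher and mesenchymal genes lower in shDap5 cells. Rab25, a small GTPase of epithelial recycling endosomes, rose from 14.4 ± 0.581 to 81.6 ± 6.77 CPM (SD, n = 3 each), and Krt14, a basal cell keratin, from 7.26 ± 1.02 to 35.8 ± 7.46. Vim, the intermediate filament protein vimentin of mesenchymal cells, fell from 2033 ± 102 to 888 ± 58.3 CPM, and Sparc, a matricellular glycoprotein, from 184 ± 1.97 to 81.8 ± 9.45. Angiogenesis genes were also lower. By camera the hypoxia list was lower (adjusted p = 0.00307; adjusted p = 0.675 with an estimated correlation, and 0.218 without shDap5 2). Cholesterol synthesis genes were higher in 2 of the 3 shDap5 inputs (camera adjusted p = 2.24e-06; adjusted p = 0.792 with an estimated correlation).

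Of the 29 tested epithelial markers 14 rose and 1 fell (22 and 2 adjusted over the list alone), with a median log2 change of 0.62 (camera adjusted p = 1.23e-15; adjusted p = 0.033 with an estimated correlation). Rab25 rose by a log2 change of 2.50 (SE 0.24, edgeR adjusted p = 1.24e-05), and Krt14 by 2.30 (SE 0.26, adjusted p = 3.5e-05). Esrp2, a regulator of epithelial splicing, rose by 1.11 (SE 0.14, edgeR adjusted p = 1e-04). Tjp3, the tight junction scaffold ZO-3, went the other way, from 11.9 ± 0.847 to 2.23 ± 1.3 CPM (log2 -2.42, SE 0.31, edgeR adjusted p = 9.39e-05). Of 19 mesenchymal genes 5 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.89 (camera adjusted p = 0.000101; adjusted p = 0.033 with an estimated correlation). The falls included Fstl1, a secreted follistatin-like protein (log2 -2.39, SE 0.32, edgeR adjusted p = 0.000204), and Col5a1, a chain of type V collagen (-1.78, SE 0.29, adjusted p = 0.00095). Vim (-1.20, SE 0.20, edgeR adjusted p = 0.00141) and Sparc (-1.17, SE 0.19, adjusted p = 0.000755) were among them as well. The list's median was -1.19, -0.36 and -1.16 in shDap5 inputs 1, 2 and 3 against the NSi input of the same number.

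Of 23 angiogenic factors 2 fell and 0 rose (4 and 0 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.00849; adjusted p = 0.0424 with an estimated correlation). These were Angpt1, the ligand of the endothelial receptor Tie2 (log2 -3.50, SE 0.48, edgeR adjusted p = 0.000225), and Ecm1, an extracellular matrix protein (-0.64, SE 0.14, adjusted p = 0.0101). Vegfa, the main endothelial growth factor, was at -0.51 (edgeR adjusted p = 0.0667). Markers of endothelial cells moved the same way at low levels: 2 of 7 fell and the median was -0.53 (camera adjusted p = 0.0773, fry adjusted p = 0.0213), or -0.058, -1.17 and -0.22 for numbers 1, 2 and 3. The falls were in Vwf (mean 0.26 CPM, log2 -2.25, SE 0.46, edgeR adjusted p = 0.00539), a clotting factor carrier, and Tie1, a receptor (mean 0.946 CPM, -1.96, SE 0.48, adjusted p = 0.0172). All 4 tested fibroblast markers lay below 0 (median -0.51, camera adjusted p = 0.289). Of 28 hypoxia and glycolysis genes 3 fell (4 adjusted over the list alone) and 0 rose, with a median of -0.14 (camera adjusted p = 0.00307; adjusted p = 0.675 with an estimated correlation). These were Eno2, an enolase (log2 -1.81, SE 0.21, edgeR adjusted p = 4.18e-05), P4ha2, a collagen prolyl hydroxylase subunit (-1.75, SE 0.23, adjusted p = 0.000133), and Egln3, an oxygen-sensing prolyl hydroxylase (-0.86, SE 0.18, adjusted p = 0.00526). Most of the hypoxia shift came from shDap5 input 2 (median -0.62, against -0.067 and -0.011 for numbers 1 and 3). The camera call was lost without arm and number shDap5 2 (adjusted p = 0.218) or without that input alone (adjusted p = 0.231). Cholesterol synthesis genes had a median of 0.72 (camera adjusted p = 2.24e-06; adjusted p = 0.792 with an estimated correlation). Their medians by number were 0.87, 0.045 and 1.03, so shDap5 input 2 stood apart here too. Of 24 members 2 rose. They were Stard4, a sterol transfer protein (log2 1.0, SE 0.24, edgeR adjusted p = 0.0162), and Idi1, an isomerase of the isoprenoid pathway (1.24, SE 0.32, adjusted p = 0.0229).

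Single genes are ranked here among those called with a mean of at least 5 CPM and no overlap between the arms. The largest rises were in Slc26a9, an epithelial anion transporter (log2 3.50, SE 0.50, edgeR adjusted p = 0.000335), Cwh43 (2.75), 1700024P16Rik (2.75) and Serpina3h of the serpin protease inhibitors (2.72). Next came Dock11, an activator of the GTPase Cdc42 (2.64), Cobl, an actin nucleator (2.55), Ap1m2, a clathrin adaptor subunit of epithelial cells (2.51), Rab25, Adam12, a metalloprotease (2.47), and Il18rap, a subunit of the receptor of interleukin-18 (2.45). Among the largest falls were Tspan7, a tetraspanin (log2 -2.92, SE 0.36, edgeR adjusted p = 7.9e-05), and Mt2, a metallothionein (-2.91). Gnao1, a G protein subunit (-2.74), Fam129a (-2.66) and Hsd17b11, a lipid droplet dehydrogenase (-2.59, SE 0.20, edgeR adjusted p = 1.27e-06), followed, as did Nov, a matricellular protein (-2.53), Sema3b, a semaphorin (-2.48), Tjp3 and Ston2, an endocytic adaptor (-2.40). Reads of Serpina3h may be shared with its near-identical neighbours.

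In all, edgeR called 1047 of 15072 genes in input, 453 higher and 594 lower in shDap5. Of these, 717 differed by at least 2-fold. With replicate number as a block the count was 1798, with a block within each fraction 3330, and with only the 6 input libraries 2158. The count was 542, 530 and 584 without NSi 1, 2 and 3, and 427, 2005 and 564 without shDap5 1, 2 and 3. It was 1740 without shDap5 input 2 alone and 515 without shDap5 input 3 alone. Some calls were lost with at least 1 arm and number left out, all in the same direction, and the highest adjusted p among the 6 is given for each. By edgeR these were Mt2 (adjusted p = 0.176 without shDap5 3, and 0.0547 with replicate number as a block), Fam129a (0.185 without shDap5 1), Idi1 (0.158 without shDap5 3), Stard4 (0.152 without shDap5 1), Tie1 (0.094 without shDap5 3), Vwf (0.0515 without NSi 2) and Ecm1 (0.0547 without shDap5 1).

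**Figure D2:**
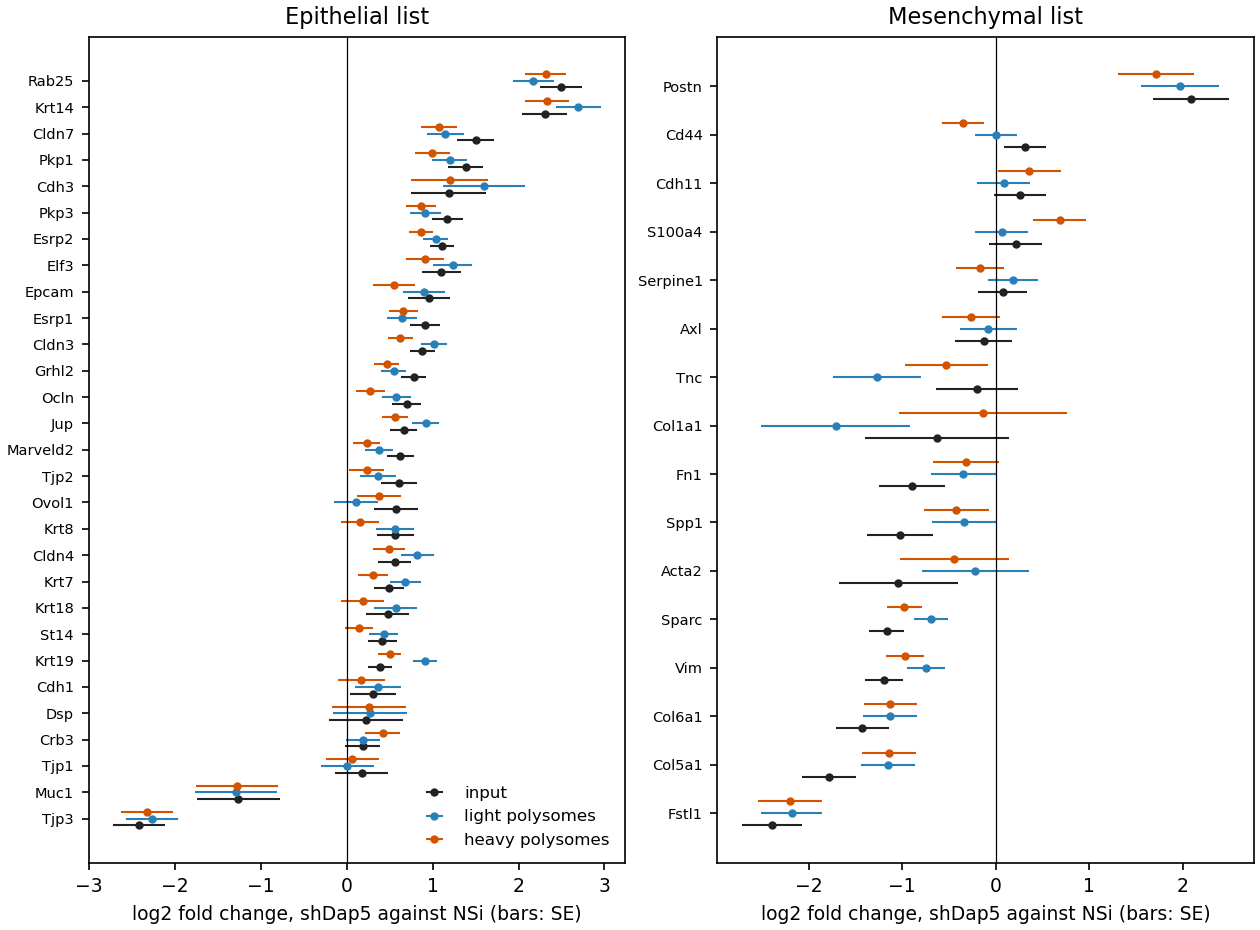
Log2 change (shDap5 against NSi, with SE) of the epithelial and mesenchymal markers that reach 1 CPM, in input (black), light (blue) and heavy polysomes (orange). Krt14 and Rab25 lie above 2 in all 3 fractions, and Tjp3 and Fstl1 below -2.

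On light polysomes the question was which mRNAs were more or less abundant among transcripts with few ribosomes. Epithelial markers were again higher in shDap5, led by Krt14 (log2 2.70, SE 0.26, edgeR adjusted p = 2.06e-05) and Rab25 (2.17, SE 0.24, adjusted p = 6.62e-05). Mesenchymal markers were lower (camera adjusted p = 0.00434; adjusted p = 0.159 with an estimated correlation), led by Fstl1 (-2.18, SE 0.32, edgeR adjusted p = 0.00105). Single genes are ranked on light polysomes as in input, at a mean of at least 5 CPM. The largest rises beside Krt14 were in Nox4, an oxidase that makes hydrogen peroxide (2.59, SE 0.25, edgeR adjusted p = 2.06e-05), and Cobl (2.53, SE 0.29, adjusted p = 9.79e-05). Then came Slc26a9 (2.30, SE 0.48, edgeR adjusted p = 0.0122) and Rarb, a retinoic acid receptor (2.30, SE 0.30, adjusted p = 0.000408). The largest falls were in Tjp3 (-2.27, SE 0.31, edgeR adjusted p = 0.000447), Fstl1 and Tspan7 (-2.09, SE 0.36, adjusted p = 0.00279). Then came Ldhb, a lactate dehydrogenase subunit (-2.07, SE 0.34, edgeR adjusted p = 0.00219), and Tmem98, a membrane protein (-2.03, SE 0.22, adjusted p = 6.62e-05).

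Of 29 epithelial markers 14 rose and 1 fell on light polysomes (21 and 2 adjusted over the list alone), with a median log2 change of 0.64 (camera adjusted p = 2.18e-21; adjusted p = 0.0198 with an estimated correlation). Of 19 mesenchymal genes 5 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.69 (camera adjusted p = 0.00434; adjusted p = 0.159 with an estimated correlation). The rise was in Postn, a matricellular protein (log2 1.97, SE 0.42, edgeR adjusted p = 0.0135). The falls included Col5a1 (-1.15, edgeR adjusted p = 0.034) and Col6a1, a chain of type VI collagen (-1.13, adjusted p = 0.0394). Of 28 hypoxia and glycolysis genes 3 fell and 0 rose (P4ha2 -1.31, Eno2 -1.12, Egln3 -0.88), with a list median of -0.24 (camera adjusted p = 0.00434; adjusted p = 0.623 with an estimated correlation). Interferon-stimulated genes had a median of 0.56 (camera adjusted p = 0.00564; adjusted p = 0.956 with an estimated correlation), and 0 of 33 members were called by edgeR. Their medians were -0.26, 1.0 and 0.66 for numbers 1, 2 and 3. The 7 mitochondrially encoded mRNAs had a median of -0.69 (camera adjusted p = 0.0239; adjusted p = 0.824 with an estimated correlation) with 0 members called by edgeR. Mitochondrial reads made up 1.57 to 3.61% of NSi and 0.955 to 2.71% of shDap5 light libraries.

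In all, edgeR called 523 genes on light polysomes, 276 higher and 247 lower, and 351 differed by at least 2-fold. The count was 1013 with replicate number as a block, 2431 with a block within each fraction and 237 with only the light libraries. It was 268, 159 and 256 without NSi 1, 2 and 3, and 303 and 237 without shDap5 1 and 3. The interferon call was lost with the block within fraction (camera adjusted p = 0.0866), without NSi 2 (0.102) and without shDap5 3 (0.228). The mitochondrial call was lost without NSi 1 (0.147), NSi 3 (0.105), shDap5 2 (0.208) and shDap5 3 (0.0917). Named genes lost a call too, here with the highest adjusted p for each. The edgeR calls of Col5a1 (adjusted p = 0.172), Postn (0.106), Egln3 (0.0922), P4ha2 (0.0626) and Eno2 (0.0577) were lost without NSi 2. That of Col6a1 was lost without NSi 3 (0.224) and that of Slc26a9 without NSi 1 (0.0817).

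Heavy polysomes carry the mRNAs with the most ribosomes. The comparison there asked how their makeup differed in cells with the hairpin against Dap5. Single genes are ranked on heavy polysomes as in input, at a mean of at least 5 CPM. Nox4 (log2 2.71, SE 0.25, edgeR adjusted p = 1.38e-05), Cobl (2.60, SE 0.29, adjusted p = 5.48e-05), Krt14 (2.33, SE 0.26, adjusted p = 4.44e-05) and Rab25 (2.32, SE 0.24, adjusted p = 2.59e-05) rose most. Close to them were Mal, a proteolipid of apical transport (2.31, SE 0.22, edgeR adjusted p = 1.69e-05), and Slc4a4, a bicarbonate cotransporter (2.13, SE 0.32, adjusted p = 0.00113). Further rises were in Blnk, an adaptor of B cell signalling (2.04), Chn2, a Rac GTPase-activating protein (1.97), and P3h4, which takes part in collagen hydroxylation (1.90). Tjp3 (-2.33, SE 0.30, edgeR adjusted p = 0.000249), Otop1, a proton channel (-2.22, SE 0.34, adjusted p = 0.0012), and Tspan7 (-2.19) fell most. Further falls were in Cpq, a secreted carboxypeptidase (-2.05, SE 0.18, edgeR adjusted p = 8.29e-06), and Ank2, an ankyrin (-2.03), and in Ldhb (-1.98), Hsd17b11 (-1.95), Armcx4 (-1.86) and Gnao1 (-1.84).

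Of 29 epithelial markers 10 rose and 1 fell on heavy polysomes (14 and 2 adjusted over the list alone), with a median log2 change of 0.46 (camera adjusted p = 1.11e-10; adjusted p = 0.0944 with an estimated correlation). Esrp2 was among the rises (0.86, SE 0.14, edgeR adjusted p = 0.00196). Of 28 hypoxia and glycolysis genes 3 fell (6 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 2.05e-08; adjusted p = 0.0944 with an estimated correlation). They were P4ha2 (log2 -1.53), Eno2 (-1.41) and Egln3 (-0.74). Of 19 mesenchymal genes 5 fell and 1 rose, also adjusted over the list alone, with a median of -0.42 (camera adjusted p = 0.00302; adjusted p = 0.0944 with an estimated correlation). Fstl1 (-2.20, SE 0.34, edgeR adjusted p = 0.00132), Sparc (-0.98, SE 0.19, adjusted p = 0.00563) and Vim (-0.97, SE 0.20, adjusted p = 0.0111) fell and Postn rose (1.71, SE 0.41, adjusted p = 0.0236). Of 23 angiogenic factors 2 fell, Angpt1 (-2.31, edgeR adjusted p = 0.0139) and Ecm1 (-0.62, adjusted p = 0.0196). The list's median was -0.25 (camera adjusted p = 0.0307; adjusted p = 0.0944 with an estimated correlation). Endothelial markers lay lower still but were not called, with 6 of 7 below 0 and a median of -0.73 (camera adjusted p = 0.402), or -0.41 (0.377) on light polysomes. S phase genes had a median of -0.26 (camera adjusted p = 0.0185; adjusted p = 0.983 with an estimated correlation) with 0 of 36 members called by edgeR. The replication helicase subunit Mcm2 was at -0.59 (edgeR adjusted p = 0.136). Interferon-stimulated genes had a median of 0.42 (camera adjusted p = 0.0307; adjusted p = 0.983 with an estimated correlation) with 0 of 33 members called by edgeR. Their medians were -0.42, 1.0 and 0.68 for numbers 1, 2 and 3.

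In all, edgeR called 595 genes on heavy polysomes, 306 higher and 289 lower, and 390 differed by at least 2-fold. The count was 1122 with replicate number as a block, 2765 with a block within each fraction and 52 with only the heavy libraries. The main fit shares the spread between all groups, and replicates differed more on heavy polysomes than in NSi inputs. It was 312 and 174 without NSi 1 and 2, and 293 and 294 without shDap5 1 and 3. The angiogenesis call was lost with the block within fraction (camera adjusted p = 0.0554) and without shDap5 1 (0.155). The S phase call was lost without NSi 1 (0.282) and shDap5 3 (0.56). The interferon call was lost with replicate number as a block (0.0856), with the block within fraction (0.155), and without NSi 2 (0.184), shDap5 2 (0.12) and shDap5 3 (0.56). Named genes also lost a call, here with the highest adjusted p for each. The edgeR calls of Egln3 (adjusted p = 0.204), Postn (0.161), Angpt1 (0.111), Vim (0.0922), Gnao1 (0.087), Armcx4 (0.0835) and Sparc (0.0547) were lost without NSi 2. That of Ecm1 was lost without shDap5 1 (0.122) and that of Ank2 without NSi 1 (0.1).

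The 3 fractions shared much of their difference between the arms. Of 1322 genes called in at least 1 fraction, 147 were higher and 147 lower in shDap5 in all 3, and 0 were called in opposite directions. Among the genes called in all 3 were Rab25, Krt14 and Cobl on the higher side and Tjp3, Fstl1, Tspan7 and Hsd17b11 on the lower side. Input and heavy polysomes shared 188 higher and 234 lower genes, where independent calls would share 9.2 and 11.4. Input and light polysomes shared 187 and 190 (8.3 and 9.73 if independent), and light and heavy polysomes 180 and 158 (5.6 and 4.74 if independent). Across genes, which are not independent replicates, log2 changes in input and on heavy polysomes had a Pearson correlation of 0.705 and a Spearman correlation of 0.627 (9877 genes). The values were 0.727 and 0.598 for input and light polysomes (9993 genes), and 0.806 and 0.735 for light and heavy polysomes (9920 genes). Light and heavy libraries of the same number also deviated together within an arm, so those 2 fractions are not independent of each other.

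**Figure D3:**
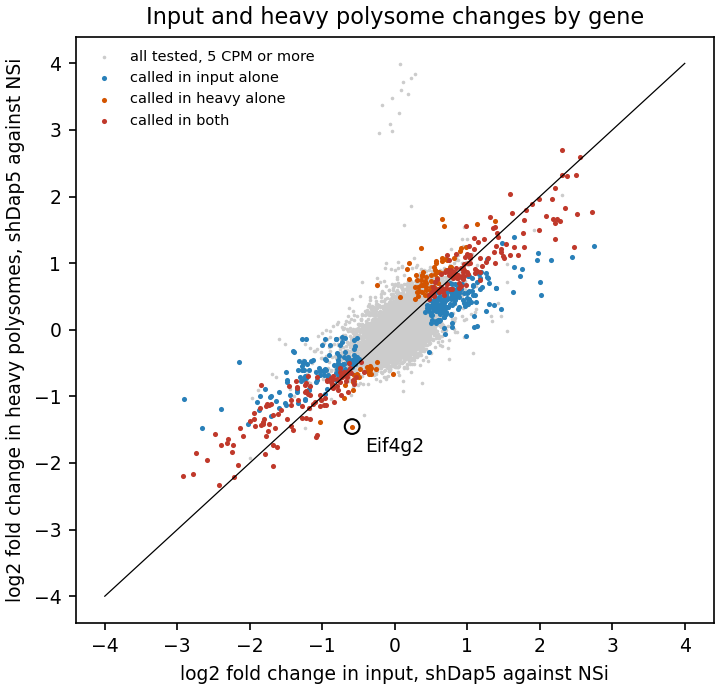
Log2 change (shDap5 against NSi) in input against that on heavy polysomes for tested genes at 5 CPM or more in both; grey not called, blue called in input alone, orange called on heavy polysomes alone, red called in both, with the line of equal change and Eif4g2 circled. Genes called in both lie along the line, and a grey group near 0 in input and between 3 and 4 on heavy polysomes was high in a single library, shDap5 heavy 2.

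Whether polysome association changed beyond the amount of mRNA, the question of translational control by DAP5, was asked with the interaction of arm and fraction. Each library was scaled by TMM, so a gain or loss shared by most mRNAs was not measured. Only changes of genes or lists against the other genes can be seen. For single genes no such change passed the test. Fry called 0 of 31 lists in each relative comparison, so the list calls below rest on camera alone. The cholesterol synthesis list was lower on heavy polysomes relative to input, with 24 of 24 members below 0 (median log2 -0.72, camera adjusted p = 1.78e-13; adjusted p = 0.68 with an estimated correlation). On heavy polysomes themselves that list did not fall (median -0.009, camera adjusted p = 0.964), and the relative change mirrors its higher level in shDap5 inputs 1 and 3. The S phase list was also lower relative to input, with 36 of 36 members below 0 (median -0.48, camera adjusted p = 2.56e-12; adjusted p = 0.68 with an estimated correlation). Its medians were 0.25 in input (camera adjusted p = 0.0778) and -0.26 on heavy polysomes (0.0185; adjusted p = 0.983 with an estimated correlation). In number 2 both lists stood near 0. Cholesterol synthesis was at -1.09, 0.057 and -0.86 and S phase at -0.60, 0.054 and -0.78 for numbers 1, 2 and 3. Members with the smallest p-values were Idi1 (-1.30) and Hsd17b7, an enzyme of the late cholesterol pathway (-1.17), in the cholesterol list. In the S phase list they were Mcm5 of the replication helicase (-0.67) and Slbp, which binds histone mRNA (-0.61). These had an edgeR adjusted p of 1.

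Further lists were called on heavy polysomes relative to input, at smaller medians. G2 and mitosis genes were at -0.22 (camera adjusted p = 1.17e-05; adjusted p = 0.68 with an estimated correlation) and epithelial markers at -0.19 (camera adjusted p = 0.00781; adjusted p = 0.68 with an estimated correlation). By the same test hypoxia and glycolysis genes were at -0.22 (camera adjusted p = 0.0394; adjusted p = 0.747 with an estimated correlation). In number 2 these lists too stood near 0. The medians for numbers 1, 2 and 3 were -0.42, 0.040 and -0.31 (G2 and mitosis), -0.41, 0.049 and -0.23 (epithelial markers) and -0.41, 0.026 and -0.26 (hypoxia). Genes of the integrated stress response, a program run by the factor ATF4, were at 0.24 (camera adjusted p = 0.022; adjusted p = 0.68 with an estimated correlation). Atf5, a transcription factor of that response (0.86), and Pck2, a mitochondrial carboxykinase (0.67), had the smallest p-values in it. By the same test the ribosomal proteins (median -0.092, camera adjusted p = 0.209), other mRNAs with 5' terminal oligopyrimidine tracts (-0.16, 0.149), initiation factors (-0.11, 0.307) and the mTOR pathway (-0.012, 0.979) were not called. For ribosomal proteins that depended on the setting. With a trend with coding length and GC content removed, a setting added after the data were seen that covers 29 lists, they were called lower (median -0.22, camera adjusted p = 8e-05; with a block within fraction -0.24, 4.34e-07). The other oligopyrimidine mRNAs were at -0.22 (camera adjusted p = 0.118) with that setting, and were called with the block within fraction as well (-0.21, 0.0117). The hypoxia call was lost with it (-0.26, camera adjusted p = 0.118) although the median did not shrink, and the same 29 lists without it gave 0.0532. An estimated correlation was not tried with the trend removed. Also not called in the fit without these settings were mesenchymal genes (0.19, camera adjusted p = 0.241), the transcription factors of the epithelial-mesenchymal transition (0.078, 0.507) and 4 fibroblast markers, all above 0 (0.52, 0.218). Of 11 genes named in earlier work as targets of DAP5 or its partner eIF3d, edgeR called 0 on heavy polysomes relative to input, in input, on light or on heavy polysomes. The list medians were -0.02, 0.057, -0.11 and 0.025 (camera adjusted p = 0.863, 0.745, 0.839 and 0.964). Adjusted over the list alone, 1 of them was called on heavy polysomes, the apoptosis inhibitor Birc2 (log2 0.48, edgeR adjusted p = 0.0729 over all genes and 0.0411 over the list). The kinase Cdk1 was at -0.57 (SE 0.26) on heavy polysomes relative to input with an edgeR adjusted p of 1.

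With edgeR, 0 of 15072 genes were called on heavy polysomes relative to input, with 295 at an unadjusted p under 0.05. DESeq2 called 0, with 360 at an unadjusted p under 0.05. With a block within each fraction edgeR called 0 (1571 unadjusted). Without arm and number shDap5 2 it called 13, or 9 without shDap5 input 2 alone. The genes with the smallest p-values were Cst6, a protease inhibitor (log2 0.92), Nqo1, a quinone reductase (1.01), Bscl2, the lipid droplet protein seipin (0.86), Ggact (0.68) and the multi-copy histone gene Hist1h2bc (1.0) on the higher side. On the lower side they were Ptbp2, a splicing regulator (-0.80), Neil3, a DNA glycosylase (-0.76), Gramd2 (-0.88), Pask, a kinase (-0.67), and Kpna2, an importin with pseudogene copies (-1.37). Each of the 10 had an edgeR adjusted p of 1. Camera calls were lost for epithelial markers without NSi 1 (adjusted p = 0.328) and without shDap5 input 2 (0.142), and for the stress response without NSi 3 (0.329) and shDap5 1 (0.119). They were also lost for G2 and mitosis without shDap5 3 (0.367), and for hypoxia without NSi 1 (0.516), NSi 2 (0.199), shDap5 3 (0.714) and shDap5 input 3 (0.19).

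For light polysomes relative to input, which draws on the same 6 input libraries, S phase genes were at a median of -0.41 (camera adjusted p = 2.45e-07; adjusted p = 0.639 with an estimated correlation) and cholesterol synthesis at -0.61 (camera adjusted p = 3.41e-07; adjusted p = 0.639 with an estimated correlation). G2 and mitosis genes were at -0.22 (camera adjusted p = 0.000864; adjusted p = 0.639 with an estimated correlation). On light polysomes themselves the changes of these lists were -0.17, 0.17 and -0.040 (camera adjusted p = 0.218, 0.329 and 0.675), so cholesterol synthesis genes did not fall there. For numbers 1, 2 and 3 the medians were -0.33, 0.022 and -0.82 (S phase), -1.03, 0.15 and -0.74 (cholesterol synthesis) and -0.23, -0.043 and -0.45 (G2 and mitosis). Epithelial markers (median -0.003, camera adjusted p = 0.841) and hypoxia genes (-0.010, 0.699) were not called relative to input. Mitochondrially encoded mRNAs were at -0.92 (camera adjusted p = 3.45e-05; adjusted p = 0.639 with an estimated correlation) and the integrated stress response at 0.33 (camera adjusted p = 6.41e-05; adjusted p = 0.639 with an estimated correlation). The mitochondrial value is not read here as a change in the number of ribosomes on these mRNAs. Single genes with the smallest p-values were Ndrg4 (0.80), Tecpr1, an autophagy protein (0.88), Gprc5b, an orphan receptor (1.11), Igfbp7, a secreted binding protein of insulin-like growth factors (0.91), and Mlycd, a malonyl-CoA decarboxylase (0.78). On the lower side they were Zfpm2, a GATA cofactor (-1.36), LOC105246307 (-0.78), Neil3 (-0.61), Malat1 (-1.25) and Dclre1b, a telomere nuclease (-0.81). All 10 had an edgeR adjusted p of 1. Zfpm2 alone among these was called with a library left out (edgeR adjusted p = 0.0242 without shDap5 2 and 0.00794 without shDap5 input 2). By edgeR 0 genes were called, with 320 at an unadjusted p under 0.05, and by DESeq2 0, with 400. Without shDap5 2 edgeR called 11, and without shDap5 input 2 alone 9. Camera calls were lost for S phase without shDap5 3 (adjusted p = 0.0899), and for G2 and mitosis without NSi 2 (0.0967), shDap5 3 (0.622) and shDap5 input 3 (0.0586). The call of mitochondrial mRNAs was lost without shDap5 2 (0.222) and shDap5 input 2 (0.0674).

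A shift between light and heavy polysomes could mark nuclear-encoded mRNAs that gained or lost ribosomes. Epithelial markers were at -0.19 on heavy relative to light polysomes (camera adjusted p = 0.000771; adjusted p = 0.661 with an estimated correlation), and hypoxia and glycolysis genes at -0.23 (camera adjusted p = 0.00204; adjusted p = 0.661 with an estimated correlation). Matrix proteases and their inhibitors were at -0.22 (camera adjusted p = 0.0208; adjusted p = 0.243 with an estimated correlation) and integrins at -0.20 (camera adjusted p = 0.0257; adjusted p = 0.875 with an estimated correlation). Mitochondrially encoded mRNAs, to which that reading does not apply, were at 0.57 (camera adjusted p = 0.0257; adjusted p = 0.875 with an estimated correlation). With the trend with coding length and GC content removed, the calls of integrins (median -0.17, camera adjusted p = 0.0907) and proteases (-0.20, 0.0835) were lost at medians of much the same size, which does not single out that trend as their source. With a block within fraction as well both were called (camera adjusted p = 0.0456 and 0.0226). Epithelial markers stayed past the threshold but shrank from -0.19 to -0.12 (camera adjusted p = 0.0171), and hypoxia genes went from -0.23 to -0.19 (0.0377). With that setting ribosomal proteins went from 0.010 (camera adjusted p = 0.404), not called, to -0.20 (1.25e-06), and the other oligopyrimidine mRNAs from -0.22 (0.0624) to -0.23 (0.0346). Eif4g2 was at 0.14 (SE 0.36, edgeR adjusted p = 1). The genes with the smallest p-values were Dynlt3, a dynein light chain (0.65), Ggact (0.78), Zfp760 (0.69), Pcnp (0.53) and Crls1, the cardiolipin synthase (0.70). On the lower side they were Alg1, a mannosyltransferase of glycan assembly (-0.53), Plod3, a lysyl hydroxylase (-0.53), Aga, a lysosomal amidase (-0.48), Zc3h7b (-0.50) and Amacr, a racemase of fatty acid breakdown (-0.68). The edgeR adjusted p was 1 for all 10. By edgeR 0 genes were called, with 181 at an unadjusted p under 0.05, and by DESeq2 0, with 223. Camera calls were lost for integrins without NSi 1 (adjusted p = 0.742), NSi 2 (0.158), shDap5 1 (0.084) and shDap5 3 (0.409). Those of proteases were lost without NSi 1 (0.297), shDap5 1 (0.0649) and shDap5 3 (0.0549), and that of mitochondrial mRNAs without NSi 3 (0.847) and shDap5 2 (0.168).

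In control cells the 2 polysome pools differed widely, which gives the background for the shifts above. Higher on heavy polysomes were Pfkl, the liver phosphofructokinase (log2 2.71, SE 0.28, edgeR adjusted p = 7.87e-07), and Mvp, the major vault protein (2.65, SE 0.21, adjusted p = 1.09e-07). So were Anxa11, an annexin (2.56, SE 0.17, edgeR adjusted p = 6.22e-08), Lgals3bp, a secreted glycoprotein (2.51), and Cad, the large enzyme that starts pyrimidine synthesis (2.46). Higher on light polysomes were Tmsb4x, the small actin-binding protein thymosin beta 4 (-2.60, SE 0.39, edgeR adjusted p = 3.15e-05), and Lst1 (-2.60). So were Snhg3, a noncoding host of small nucleolar RNA (-2.58), Myeov2 (-2.54), and Usmg5, a small subunit of the mitochondrial ATP synthase (-2.48). By edgeR 7930 genes were called, 4065 higher and 3865 lower on heavy polysomes, and 4444 differed by at least 2-fold. With total counts in place of TMM, which moved the median of all genes from -0.028 to -0.25, it was 7802 genes with 37.6% higher in place of 51.3%. Tmsb4x and Usmg5 reversed to 0.58 and 0.56 in a fit with a trend with coding length and GC content removed and a block within fraction. Eif4g2 was at -0.39 (edgeR adjusted p = 0.209). It passed with a block within fraction (-0.49, edgeR adjusted p = 0.048) and with total counts (-0.61, adjusted p = 0.0426). A block within fraction sets the pools against each other at number 1 and not at the mean of the numbers. Eif4g2 was at -0.606 in number 1, -0.258 in number 2 and -0.222 in number 3. Within libraries, the level of a gene against its mean correlated with coding length across genes (Spearman 0.36 to 0.491 in the inputs, -0.36 to -0.593 on light polysomes). On heavy polysomes the correlation was 0.197, 0.289 and -0.175 in NSi 1, 2 and 3 and -0.065, 0.318 and -0.265 in shDap5 1, 2 and 3.

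**Figure D4:**
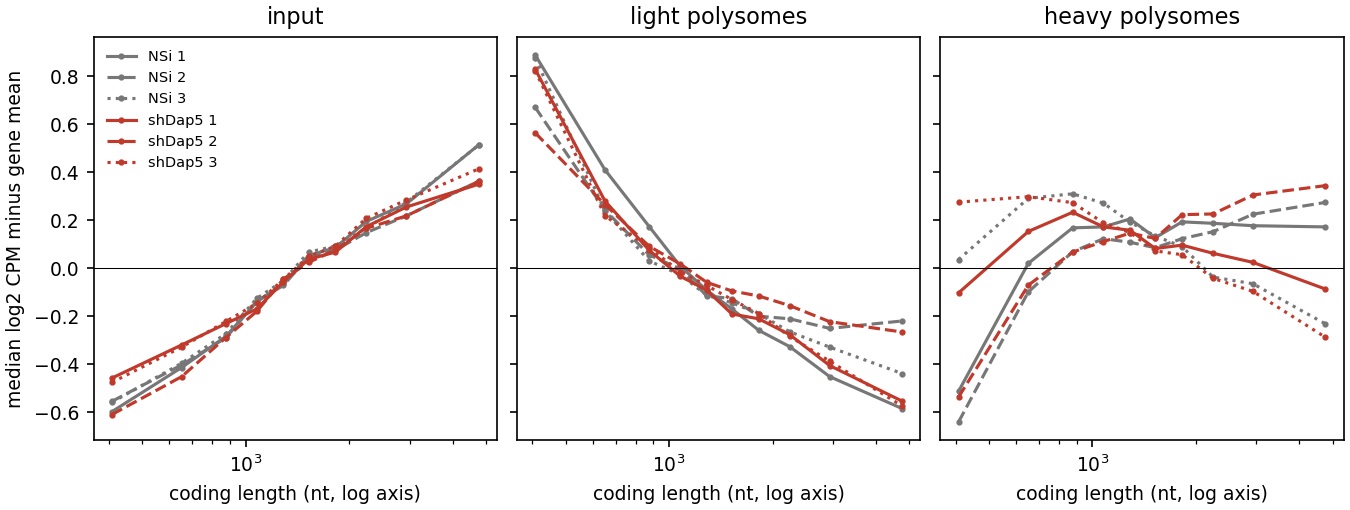
Median log2 CPM minus the gene's mean, by coding length in 10 bins (log axis), for each library in input, light and heavy polysomes. Light libraries fall with coding length and input libraries rise, while heavy libraries differ among themselves within both arms.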

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

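Among the tests below, those on other cell types, on the lines before induction, on single arms and numbers, on single shDap5 inputs and on control-cell RNA by genes at 5 CPM or more, and the fits without 1 shDap5 input or with a block within fraction, were chosen after the results they measure were seen.

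Eif4g2 stood at 66.5% of the NSi level in shDap5 inputs but at 33.1% on light and 36.5% on heavy polysomes, although the difference itself was not called by edgeR over all genes (-0.86 on heavy polysomes relative to input, adjusted p = 1). A mislabelled input library is argued against: over 307 genes called on light polysomes, the median signed log2 difference from the NSi inputs was 0.868, 0.972 and 0.866 in the 3 shDap5 inputs and -0.017 to 0.035 in the NSi inputs. Control-cell RNA in the shDap5 inputs is argued against by genes at 5 CPM or more. The 98 called lower on light polysomes had a median input minus heavy change of -0.186. The 47.3% of control RNA that Eif4g2 would need gives 0.622. A bootstrap over these genes gave a 95% interval of -0.299 to -0.076, which does not cover the spread between libraries. A further 11 genes, at least 8-fold lower in both shDap5 polysome fractions, had a median of 3.54% of NSi in the shDap5 inputs. These 11 lie near the counting floor and do not decide it. A single shDap5 input is not the source either, since with each left out in turn the mean of the others was 63, 78.6 and 58% of NSi. Eif4g2 RNA that is not on ribosomes, such as nuclear or partly degraded RNA, may account for it and was not tested.

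The cholesterol synthesis list (median -0.722 on heavy relative to input) and the S phase list (-0.48) stood out because the change on heavy polysomes lay below that in input by camera on the interaction. For cholesterol synthesis the difference lay in the inputs, where the median change was 0.723, and not on heavy polysomes, where it was -0.009 and the libraries of the arms overlapped. Its list medians were 0.687, -0.521 and 0.609 in shDap5 inputs 1, 2 and 3 against -0.447 to -0.17 in NSi inputs. For S phase the median change was 0.251 in input and -0.255 on heavy polysomes. The S phase list was not called in input. Its call on heavy polysomes ended with an estimated correlation and without NSi 1 or shDap5 3, so where its difference lay is open. A trend with coding length and GC content is argued against for both, with medians of -0.757 and -0.475 once it was removed (camera adjusted p = 1.58e-12 and 3.21e-11). With each arm and number left out in turn, both lists stayed called by camera with the preset correlation (highest adjusted p = 3.14e-05 and 0.0176). By that test 7 of 10 splits of the libraries, the real one among them, gave at least as many lists (below). Staying called therefore does not decide whether the difference rests on few libraries. Both calls ended with an estimated correlation (adjusted p = 0.68), and number 2 stood near 0 in both lists, so a state of the cultures that moves these genes together, such as sterol supply or growth, stays open and was not tested.

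Of all genes, 52 differed by a fitted 4-fold or more in the same direction in all 3 fractions, 24 higher and 28 lower in shDap5. A gained or lost chromosome region behind most of these genes is argued against. For the 51 with a position, the 5 nearest tested genes on each side had a median signed input change of 0.058, against 0.5 or more for such a region. A bootstrap over the 51 genes gave a 95% interval of 0.016 to 0.102, which does not cover the spread between libraries. Of 510 neighbour genes 263 went in the same direction. A region at single genes stays open, because a median over all genes does not test it. A neighbour called in the same direction was found for 21 of the 51. Cells of 6 other types in 1 arm cannot be told apart from this pattern: the highest median of the marker lists was 0.268 CPM, against a median of 1.78 CPM for these genes in the arm where they were higher, and genes at such low levels do not decide it. A difference between the 2 lines that predates the hairpin's induction cannot be told apart for the 52 genes either, because each arm is 1 line and uninduced cells were not among the samples. A response to the Dap5 hairpin remains open beside these explanations. The limit of 1 line per arm holds as well for every other difference between the arms given here.

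The other lists whose change differed between fractions, by camera on the interaction, are given as medians of log2 changes. Relative to input, heavy polysomes had epithelial markers at -0.193, G2 and mitosis at -0.218, hypoxia and glycolysis at -0.223 and the integrated stress response at 0.238. Light polysomes relative to input had S phase at -0.414, cholesterol synthesis at -0.612, G2 and mitosis at -0.223, mitochondrially encoded mRNAs at -0.924 and the integrated stress response at 0.329. Heavy relative to light polysomes had epithelial markers at -0.191, hypoxia and glycolysis at -0.227, integrins at -0.197, matrix proteases and inhibitors at -0.223 and mitochondrially encoded mRNAs at 0.568. With an estimated correlation 0 of these lists were called, at adjusted p from 0.243 to 0.875.

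Counts of called genes were set against the 10 splits of the 6 arms and numbers into 3 and 3, too few for a share under 0.05. In input 1 of 10 splits reached the real count of 1047 (highest other 0), on light polysomes 1 of 10 reached 523 (highest other 13), and for control heavy against light, with splits of the 6 control libraries, 1 of 10 reached 7930 (highest other 0). On heavy polysomes 2 of 10 reached 595: setting NSi 1, NSi 2 and shDap5 2 against the rest gave 2242 genes, which points to a structure of the samples, and those 3 heavy libraries are the ones with a positive correlation of level with coding length. That split also gave 432 genes for heavy relative to input, where the real count was 0 and 10 of 10 splits were as large; for light relative to input and heavy relative to light all 10 gave 0. Of the splits that part all 3 numbers, the 3 others gave 0 genes in each comparison of the arms, while the splits that keep a number together mix it with the arms. Every split but the real one holds libraries of both arms, or of both control pools, on each side. A difference between them then adds to the spread within groups and lowers the count. Counts of 0 in other splits therefore do not show how many calls chance alone would give. Called lists set the arms less apart from other splits: 5 lists in input (10 of 10 splits as large, highest other 10), 5 on light polysomes (7 of 10, highest 14), 6 on heavy polysomes (7 of 10, highest 13), 6 on heavy relative to input (7 of 10, highest 12), 5 on light relative to input (9 of 10, highest 12) and 5 on heavy relative to light (5 of 10, highest 10).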

How the results depend on the processing

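The fits with a block within fraction, alone or with a correction for coding length and GC content, and those without shDap5 input 2 or 3 alone were added after the data were seen. Counts of called genes in input, light and heavy were 1047, 523 and 595, against 2158, 237 and 52 with only the groups compared. That setting takes the spread from the libraries compared, while the main fit shares it between all groups. Chi-square per degree of freedom between replicates was 9.57 to 32.8 in NSi inputs and 11.9 to 132.8 in shDap5 inputs. It was 71.4 to 242.8 on NSi and 160.4 to 435.9 on shDap5 heavy polysomes. The heavy calls of the main fit thus rest in part on the spread of other fractions. With replicate number as a block the counts were 1798, 1013 and 1122 (1046, 523 and 593 of the genes called without it were kept). They were 3330, 2431 and 2765 with the block within fraction (1047, 522 and 592 kept), and 3874, 2818 and 2830 with that block and the correction. DESeq2 gave 995 on light and 1050 on heavy polysomes. With arms and numbers or single shDap5 inputs left out, counts ran from 427 (without shDap5 1) to 2005 (without shDap5 2) in input, 159 (without NSi 2) to 674 (without shDap5 input 2) on light and 174 (without NSi 2) to 795 (without shDap5 2) on heavy polysomes, and from 0 to 13 for heavy and 0 to 11 for light relative to input (both highest without shDap5 2). Beyond the construction of a setting, the cause was not tested for any of these.

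Called lists numbered 5, 5, 6, 6, 5 and 5 in input, light, heavy, heavy relative to input, light relative to input and heavy relative to light. They numbered 3, 1, 0, 0, 0 and 0 with an estimated correlation, which allows for genes of a list that vary together. With fry they numbered 4, 4, 4, 0, 0 and 0. The block within fraction gave 8 in input and 11 in heavy relative to light, and replicate number as a block 9 in heavy relative to light; the cause was not tested. The correction for coding length and GC content, also added after the data were seen, left 6, 4 and 4 of 29 lists called in heavy relative to input, light relative to input and heavy relative to light, and 7, 4 and 9 with the block within fraction as well. With the correction alone ribosomal proteins were called lower, at -0.224 in heavy relative to input and -0.202 in heavy relative to light; the cause was not tested. With libraries left out they ran from 6 to 9 in input, 3 to 8 on light, 5 to 11 on heavy, 4 to 9 in heavy relative to input, 4 to 9 in light relative to input and 3 to 11 in heavy relative to light; the cause was not tested.

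Of 191 results for named genes, all 191 had the same direction and side of the threshold with DESeq2. The number was 190 with RLE size factors and 190 with replicate number as a block. It was 183 with total counts, 177 with no filter on low counts and 150 with only the groups compared. Of the 191, 33 were in the relative comparisons, where no gene was called, so they could not lose a call. The others, apart from Eif4g2, were picked by size or p-value in these same data. Leaving out NSi 1, 2 or 3 ended 43, 58 and 36 of the calls outside those 33. Leaving out shDap5 1, 2 or 3 ended 50, 12 and 38, with 2 libraries left in an arm. Direction reversed for Eif4g2 on heavy relative to light polysomes without NSi 1 (-0.001 against 0.14, and up to 0.204 without NSi 3). The cause was not tested. Direction also reversed for Tmsb4x (0.58) and Usmg5 (0.56) in control heavy against light with the coding length and GC correction and a block within fraction. The correction removes a trend that these short mRNAs follow, and its share was not separated from that of the block. In simulated counts fitted without a block, 11.9% of 1.5-fold changes in genes at 5 CPM or more were called in input and 0% in heavy relative to input. At this depth and spread, changes of that size were thus mostly missed by that fit in input and not seen in heavy relative to input. Fits with a block were not simulated.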

Other observations

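The fits without shDap5 input 2 or with a block within fraction were chosen after the results were seen; the test of upstream AUGs was set out before its result was seen.

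Beyond the lists called in input, single members of other pathways changed there by edgeR. Among transcription factors of the epithelial-mesenchymal transition 0 of 15 rose and 1 fell, Twist1 (39.7 ± 2.04 CPM in NSi and 20.3 ± 0.14 in shDap5, SD, n = 3; log2 -0.96, SE 0.20, edgeR adjusted p = 0.00561, and 0.0552 without shDap5 1), while the list was not called (median -0.15, camera adjusted p = 0.425). Of 30 genes of the TGF-beta pathway 4 fell and 0 rose: Tgfbr3, a co-receptor (log2 -1.94, SE 0.28, edgeR adjusted p = 0.000322), Id2, an inhibitor of helix-loop-helix factors (-0.91, adjusted p = 0.00456), the ligand Tgfb2 (-1.71, adjusted p = 0.0153) and the ligand Bmp7 (-0.80, adjusted p = 0.024), with a list median of -0.016 (camera adjusted p = 0.289). With 1 arm and number left out the calls of Id2 (0.0546 without shDap5 1), Tgfb2 (0.139 without shDap5 1) and Bmp7 (0.121 without NSi 1) were lost. Of 26 NF-kB targets 6 fell and 1 rose (list median -0.19, camera adjusted p = 0.0955): the chemokine Ccl2 (-1.93, SE 0.29, edgeR adjusted p = 0.000504) and Saa3, an acute phase protein (-2.68, SE 0.47, adjusted p = 0.00182), fell, and the cytokine Il1b rose (2.18, SE 0.51, adjusted p = 0.013, and 0.147 without shDap5 1).

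Of 28 matrix proteases and inhibitors 4 rose and 1 fell in input (list median -0.035, camera adjusted p = 0.839). Adam12 rose by 2.47 (SE 0.34, edgeR adjusted p = 0.000217) and Adam8, another membrane metalloprotease, by 1.26 (SE 0.29, adjusted p = 0.0124, and 0.0768 without NSi 3), and Ctsb, the lysosomal protease cathepsin B, fell (-0.70, SE 0.17, adjusted p = 0.0167, and 0.106 without shDap5 1). Of 18 integrins 2 rose and 2 fell (list median -0.28, camera adjusted p = 0.211): Itgb4, the integrin of hemidesmosomes (0.71, SE 0.18, edgeR adjusted p = 0.0213, and 0.131 without NSi 2), and Itgb6, an activator of TGF-beta in epithelia (1.27, SE 0.35, adjusted p = 0.0319, and 0.13 without shDap5 1), rose, and Itgb7, an integrin of lymphocytes (-2.07, SE 0.41, adjusted p = 0.00425, and 0.0535 without shDap5 1), fell. Slc7a11, the cystine transporter, fell in input (-1.35, SE 0.26, edgeR adjusted p = 0.00396), and Nupr1, a stress-induced chromatin protein, rose in input (0.98, adjusted p = 0.0235, and 0.157 without NSi 1), on light (1.41, adjusted p = 0.00472, and 0.0505 without NSi 1) and on heavy polysomes (1.56, adjusted p = 0.00213).

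Without shDap5 input 2, edgeR called 9 genes on heavy and 9 on light polysomes relative to input, each with an adjusted p of 1 when all libraries were used. Chosen after their values were seen, these included Atf5 (log2 1.68 on heavy, SE 0.23, edgeR adjusted p = 0.00596; 1.68 on light, adjusted p = 0.00656), Selp, the adhesion receptor P-selectin (2.76 on heavy, adjusted p = 0.00422; 2.87 on light, adjusted p = 0.00593), and Fads2, a fatty acid desaturase (-1.40 on heavy, adjusted p = 0.00422; -1.24 on light, adjusted p = 0.00794). With all libraries Atf5 was at 0.86 on heavy and 0.86 on light polysomes relative to input.

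Several genes were high in a single library, shDap5 heavy 2, and are given here as values chosen after they were seen. On heavy polysomes Lars2 stood at 1176 ± 1910 CPM in shDap5 and 101 ± 61.6 in NSi (SD, n = 3), Cdk8 at 2828 ± 4550 and 297 ± 193, and Cmss1 at 1538 ± 2440 and 180 ± 108. For Lars2 the log2 difference between heavy libraries of the same number was -0.10, 5.02 and -0.56 for numbers 1, 2 and 3 (edgeR log2 3.54, SE 1.24, adjusted p = 0.147).

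A hypothesis set out before its test was that mRNAs with upstream AUGs in the 5' UTR depend more on DAP5 than others, so that they would be lower on heavy polysomes relative to input. The result was negative. Within 10 bins of coding length, 2752 mRNAs with at least 2 upstream AUGs lay 0.047 log2 above 4893 mRNAs with none, where a lower value was predicted. The difference was 0.105, 0.012 and 0 for numbers 1, 2 and 3, and 0.003 to 0.072 over the other splits of the arms and numbers. Annotated 5' UTRs came from GENCODE vM21, so start sites specific to 4T1 cells were not covered.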
